A study of Arabidopsis thaliana with 2 samples.

How the data were processed

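Micrococcal nuclease (MNase) digests the linkers between nucleosomes, so that sequenced protected DNA marks where nucleosomes lie. Per the labels, DNA from Arabidopsis thaliana seedlings grown for 2 to 3 weeks under long days was digested with MNase and size-selected on a 2% agarose gel. There were 2 libraries, 1 from Col-0 wild type and 1 from nrpe1, a mutant of the largest subunit of RNA polymerase V. The submitters' processing notes name Bowtie and the TAIR10 genome. The version of Bowtie, the nucleosome caller, the definition of the score and the way the libraries were joined are not given in the sources used here.

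The values analysed here are one pooled list of nucleosomes deposited by the authors, in which each nucleosome has a chromosome, a start, an end and a score, per the file headers. The score is a unit of the authors' own, and it was used only to rank nucleosomes. No column assigns a nucleosome to Col-0 or to nrpe1, and 0 columns hold values of single libraries. A comparison of nrpe1 with Col-0 was therefore not analysed here, and neither were the totals of each library, the share of organelle DNA or the overlap between libraries. The depth of each library is unknown, and with 1 library per genotype there were no replicates. Where the genotypes differ in position, a pooled list can hold both positions, so that the density of listed nucleosomes mixes occupancy with alternative positions.

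The study design had led to ratios of nrpe1 over Col-0 for genome features, gene lists and single genes. These were replaced by the number of listed nucleosome centres per kb, a measure chosen after the columns had been seen. The gene body was settled as the window for genes after gene densities had been looked at, since the gene table gives no strand and no upstream side could be defined. The gene lists and the alternatives on score, overlap, matching and gene length were fixed before the data were examined.

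Genes came from the RefSeq table of assembly TAIR10.1, which holds 37899 nuclear gene models and gives gene type, start and end. Exons, introns, untranslated regions and transposable elements were not used here, and no reference genome was used. Genes were matched by locus identifier, and 78 of the 78 genes in the 7 lists were found. To test whether list and table keep the same offset along the genome, the profile of centres at gene ends in each of 15 parts of the genome, 3 per chromosome, was compared with the profile over all genes. The best lag lay between -30 and 12 bp, and the correlation across positions at lag 0 was at least 0.933. An offset common to the whole list would not be seen by this check. Whether positions count from 0 or from 1 is not given in the sources used here, and coordinates are printed as listed.

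Windows of 500 kb were called gene-poor where their density of protein-coding genes was under 50% of the chromosome median, and arm windows otherwise. Ratios between them have 95% intervals from 1000 bootstrap draws over windows, which cover variation along the genome and not biological replication. Windows were drawn singly, although most gene-poor windows lie side by side, so these intervals may be too narrow. Differences over the 5 chromosomes were tested with an exact two-sided sign-flip test, whose smallest p is 0.0625. Distances between all pairs of centres up to 800 bp were counted, smoothed over 21 bp, and their peaks were located between 150 and 240, 320 and 420, and 500 and 610 bp. The mean spacing is the mean of the steps between successive peaks.

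Centres were assigned to annotated features. Where features overlapped, a fixed order decided, in which other non-coding RNA genes gave way to every other class of gene. Observed counts were divided by the mean count after 1000 random shifts of the whole list by 5 to 50 kb in either direction, and the central 95% of shifted lists is the reference range. The flank of a protein-coding gene was 1 kb on both sides. Each gene list was described by its median density, set against 10000 random lists of the same size matched on length decile and on gene-poor or arm location. A list was called higher or lower outside the central 95% of random medians. These percentiles describe this list of nucleosomes and are not p-values.

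The lists were RdDM machinery (18 genes of RNA-directed DNA methylation), genes known to carry RdDM (7), SWI/SNF subunits (13), Polycomb-silenced developmental genes (10), photosynthesis genes (10), housekeeping genes (10) and seed and pollen genes (10). The rule for named genes fixed beforehand ranked ratios between the genotypes and could not be applied. In its place the text names NRPE1, the 2 members of each list whose density lies farthest on a log scale from the median of protein-coding genes, and the 10 lowest and 10 highest densities among protein-coding genes of 2 kb or longer. It also names the 5 nucleosomes with the highest scores and the top-scoring ones of selected genes. This rule, and each further gene named, was chosen after the data had been seen.

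Alternatives were nucleosomes scoring at or above the median, genes of 2 kb or longer, assignment by any overlap and lists without matching. Flanks of 500 bp and 2 kb, windows of 250 kb, sequence without long unlisted stretches, gene bodies with 1 kb on both sides, the share of a gene covered and the Polycomb list without MADS-box genes were added after the data had been seen. On simulated data the mean spacing was recovered within 0.231 bp over 3 spacings. The simulation placed overlapping neighbours midway between regular ones, so it does not test the effect of overlaps at other distances. Of 50 simulated unchanged lists of 10 genes among 27444 genes 4% fell outside the central 95%, and of 50 lists at 0.6 times the density 94% did. Simulated counts were drawn independently for each gene, so these shares do not cover groups of related genes. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.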

Results

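The data are a list of nucleosomes mapped by MNase sequencing in Arabidopsis thaliana seedlings. The series has 2 libraries, 1 from Col-0 wild type and 1 from nrpe1, and its title concerns nucleosome remodelling by SWI/SNF complexes in silencing by non-coding RNA. The list pools both libraries and carries no genotype for any nucleosome, so that nrpe1 and Col-0 were not compared. All values below describe the pooled list, without replicates and at unknown depth per library. It holds 397452 nucleosomes on the 5 nuclear chromosomes, or 3.34 per kb. They number 96785 on chromosome 1, 66192 on chromosome 2, 81498 on chromosome 3, 64229 on chromosome 4 and 88748 on chromosome 5. Listed intervals ran from 120 to 180 bp, with a median of 138 bp and a median score of 0.790. Of all nucleosomes, 64.2% overlapped a listed neighbour, by a median of 40 bp per overlapping pair. The overlap never passed 49.7% of the longer interval.

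The mutated gene itself, NRPE1 (AT2G40030), which encodes the largest subunit of RNA polymerase V, held 48 listed nucleosomes on chromosome 2. Their density of 5.18 per kb was 1.29 times the median of protein-coding genes, and they covered 66.4% of the gene. The highest-scoring one lay at 16715298 to 16715431 with a score of 0.952. Without a genotype per nucleosome these values do not test the mutant label.

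Where along the chromosomes nucleosomes were listed was the first comparison that the list allowed. Gene-poor windows, most of them around the centromeres, held more listed nucleosomes than the chromosome arms. In 18.5 Mb of gene-poor windows there were 84045, or 4.54 per kb, and in 100.6 Mb of arms there were 313407, or 3.11 per kb. The ratio was 1.46 (95% interval 1.36 to 1.56). Gene-poor windows were also covered further, at 55.5% of their sequence against 39.4%, and 78.3% of their nucleosomes overlapped a neighbour, against 60.5% on the arms. Scores hardly differed, with medians of 0.787 and 0.791.

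By chromosome, the arms held 3.12 ± 0.0667 nucleosomes per kb and the gene-poor windows 4.56 ± 0.412 (SD, n = 5 chromosomes). The ratio was lowest on chromosome 1, at 1.26, and highest on chromosome 5. It was above 1 on 5 of 5 chromosomes, with p = 0.0625 in an exact two-sided sign-flip test, the smallest p that 5 chromosomes allow. Chromosome 1 alone held stretches over 10 kb without a listed nucleosome, 12 of them, the longest of 55554 bp between 14750168 and 14805720. The densest window of 50 kb was on chromosome 2, from 3300001 to 3350000, with 415 nucleosomes or 8.30 per kb. It belongs to the part of chromosome 2 known for its insertion of mitochondrial DNA, and its 500 kb window counted as arm.

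**Figure D1:**
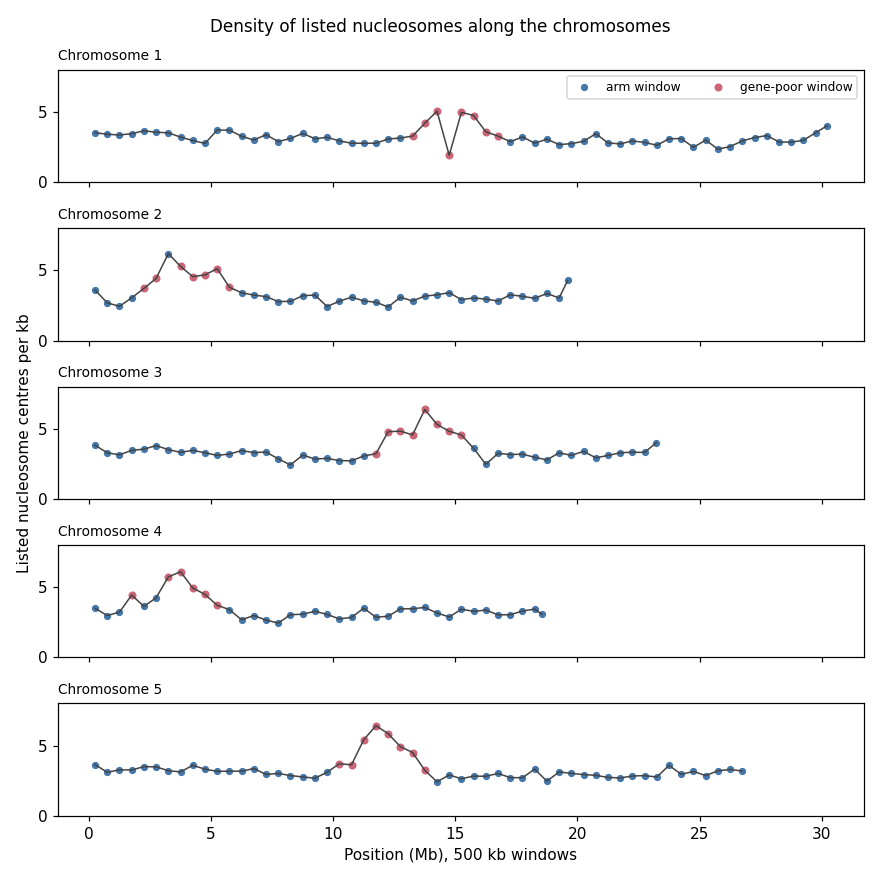
Listed nucleosome centres per kb (vertical axis) in windows of 500 kb along the 5 chromosomes (horizontal axis, Mb), with gene-poor windows in red and arm windows in blue. Arms lie near 3.11 per kb and gene-poor windows have 4.54 per kb together, with some at the density of arms, and the lowest is the chromosome 1 window that holds most of the long unlisted stretches.

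Distances between listed centres peaked repeatedly, and the first and second spacing peaks lay slightly farther out in gene-poor windows than on the arms. Over the whole list, distances between centres peaked at 191 bp (95% interval 190.3 to 191.9), 364 bp and 551 bp, a mean spacing of 180 bp (177 to 183). The first peak lay at 189 bp on the arms and at 196 bp in gene-poor windows, 7.0 bp farther (5.83 to 8.53). Within protein-coding genes it lay at 188 bp. The difference between gene-poor windows and arms was 6.96 ± 1.83 bp over chromosomes (SD, n = 5), in the same direction on 5 of 5. Among nucleosomes scoring at or above the median, the first peak lay 5.22 bp farther in gene-poor windows (3.60 to 7.13). The mean spacing, which uses the later peaks, differed by 2.57 bp with an interval from -3.09 to 7.83, so no difference was detectable in it. A further peak at 97 bp, 1.60 times as high as the first spacing peak, came from overlapping neighbours, and fell to 0.796 times that height among nucleosomes scoring at or above the median. Outside the ranges searched for spacing peaks, counts also rose to local maxima near 287 and 459 bp in gene-poor windows. On the arms such maxima lay near 274 and 472 bp. All pairs of centres were counted, so pairs that skip an overlapping neighbour can also fall in the first spacing peak. Whether the shifts of the peaks reflect spacing alone was not tested.

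**Figure D2:**
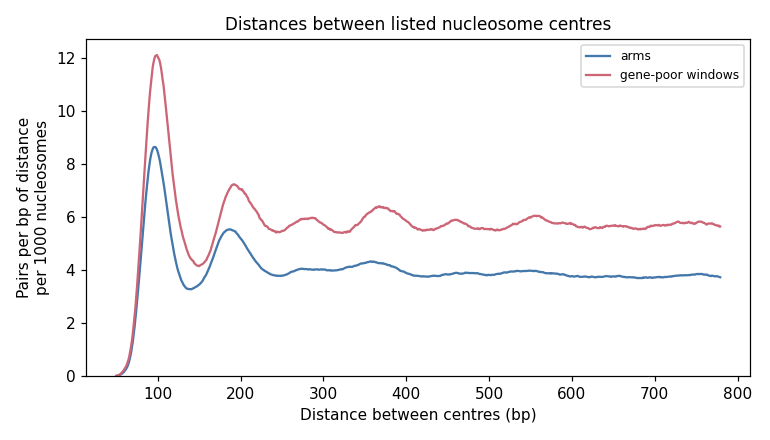
Number of pairs of listed nucleosomes per bp of distance and per 1000 nucleosomes (vertical axis) against the distance between their centres (horizontal axis, bp), for arms and gene-poor windows. Both curves peak at overlapping distances near 97 bp and then at about 189 bp on the arms and 196 bp in gene-poor windows.

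Among annotated features, tRNA genes and pseudogenes were rich in listed nucleosomes and the flanks of protein-coding genes were poor. The 625 tRNA genes held 414 centres, 8.73 per kb and 2.72 times the count after local shifts of the list (shifted range 0.861 to 1.15), or 1.70 times when assigned by any overlap. Pseudogenes held 6.48 per kb, 1.51 times the shifted count (0.983 to 1.04), and their intervals covered 77.3% of them. The excess over pseudogenes held on the arms, at 6.25 per kb and 1.92 times, and in gene-poor windows, at 6.59 per kb and 1.38 times. Transcribed pseudogenes reached 1.32 times and the 27444 protein-coding genes 1.27 times, with 259918 centres or 4.03 per kb. Protein-coding genes differed little in density between arms (4.03 per kb) and gene-poor windows (4.21 per kb). Sequence within 1 kb of a protein-coding gene fell to 1.1 per kb, 0.351 of the shifted count (0.983 to 1.01). Intergenic sequence farther away held 2.11 per kb, 0.573 of the shifted count, with 1.17 per kb on the arms against 3.45 per kb in gene-poor windows.

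Over the whole genome other small RNA genes lay inside their shifted ranges, with 1.11 for miRNA genes (0.864 to 1.14) and 0.989 for snoRNA and snRNA genes (0.849 to 1.15). On the arms alone miRNA genes lay just above theirs, at 1.17 (0.847 to 1.16). The remaining non-coding RNA genes, counted only where no other class of gene overlapped them, had 0.918 times the shifted count (0.965 to 1.04). That became 1.02 among nucleosomes scoring at or above the median. Assigned by any overlap, snoRNA and snRNA genes fell to 0.758 of the shifted count, outside the range. The gene table does not mark transposable elements, so how many pseudogenes are transposons was not determined.

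**Figure D3:**
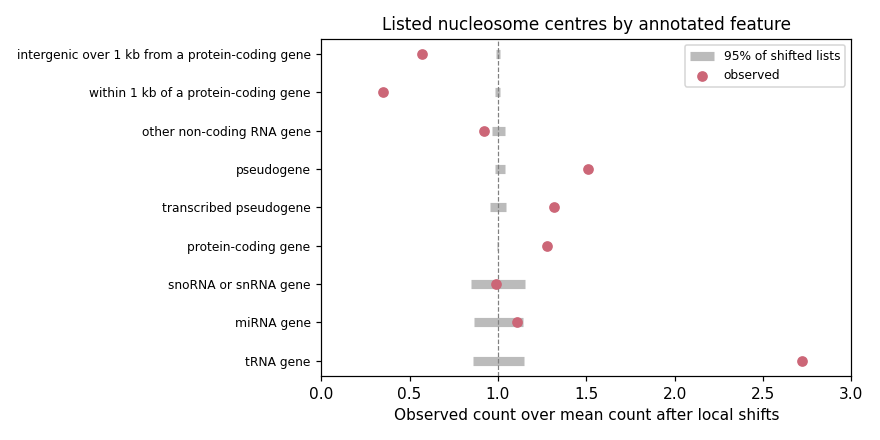
Observed number of listed nucleosome centres over the mean after local shifts of the list (horizontal axis) for 9 classes of sequence, as points, with the central 95% of shifted lists as grey bars. tRNA genes lie at 2.72 and pseudogenes at 1.51, and sequence within 1 kb of protein-coding genes at 0.351.

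Protein-coding genes were bordered by a stretch with few listed nucleosomes and carried a ridge of them just inside. Over 54888 gene ends the density was lowest 55 bp outside the gene, at 1.32 per kb, and highest 315 bp inside, at 4.90 per kb. The ridge was 3.72 times the trough. Over chromosomes the trough lay at -52.4 ± 10.04 bp, the ridge at 354 ± 45.4 bp, and their ratio was 3.96 ± 0.117 (SD, n = 5). Starts and ends of genes are mixed in these profiles, because the gene table used gives no strand.

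Around tRNA genes, which RNA polymerase III transcribes, a sharp peak stood over the gene. The density within 30 bp of the midpoint was 8.99 per kb, against 1.61 per kb at 120 to 250 bp and 3.18 per kb at 400 to 550 bp. Of the tRNA genes 66.2% had a centre inside, and 29.2% of these nucleosomes overlapped a neighbour, against 62.4% in protein-coding genes. Midpoints of miRNA genes reached 4.32 per kb, against 1.91 per kb at 120 to 250 bp. For snoRNA and snRNA genes the values were 3.07 and 1.66 per kb.

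**Figure D4:**
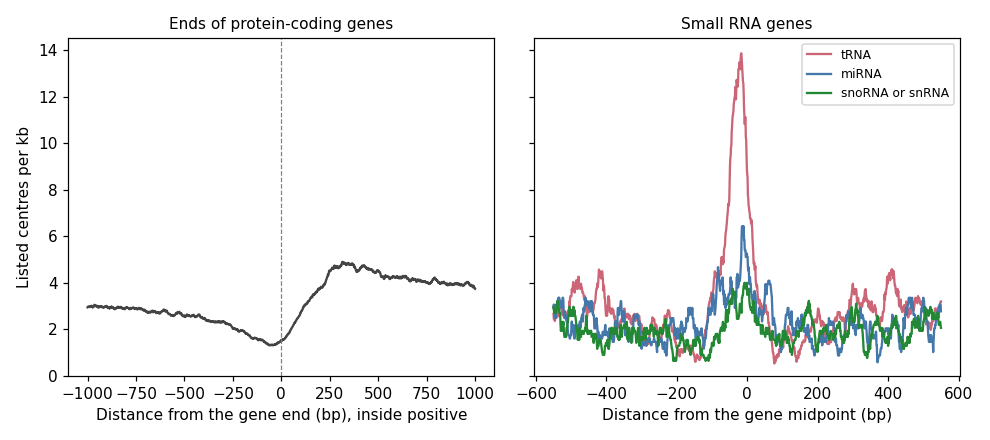
Listed nucleosome centres per kb (vertical axes) around the ends of protein-coding genes, with the inside positive (left, bp), and around the midpoints of tRNA, miRNA and snoRNA or snRNA genes (right, bp). The trough outside protein-coding genes lies at -55 bp and the ridge at 315 bp, and tRNA genes stand above the other small RNA genes. Centres in neighbouring genes are counted in the left profile.

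The SWI/SNF subunits, which form the ATP-dependent remodelling complexes named in the title, had a median of 4.85 nucleosomes per kb. That was 1.22 times the median of matched random lists and at the 98.3 percentile, with 8 of 13 members above the upper quartile of matched genes. BRM (AT2G46020), a remodelling ATPase, held 58 nucleosomes at 6.09 per kb. SWP73B (AT5G14170) held 15 at 5.96 per kb, and the lowest member was BSH (AT3G17590) with 7 at 2.74 per kb. The call did not hold for nucleosomes scoring at or above the median (96.2 percentile), with 1 kb of flank on both sides (96.9) or without matching (94.1). Such calls are common among gene groups: of 172 groups with a shared symbol, formed later, 33.1% also fell outside their random range. This limits the calls of the lists below as well.

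The RdDM machinery, to which NRPE1 belongs, had a median of 4.57 per kb, 1.16 times that of random lists. Its 97.48 percentile fell just inside the central 95%. It passed that limit, at 1.23 times, for nucleosomes scoring at or above the median, at 1.19 times with 1 kb of flank, and at 1.15 times by share covered. Without matching it stood at the 89.8 percentile, inside the range. RDR2 (AT4G11130), the RNA polymerase that makes the double-stranded precursors, held 28 nucleosomes at 6.69 per kb, and CLSY1 (AT3G42670) held 26 at 5.38 per kb. None of the 18 members lay below the lower quartile of matched genes and 6 lay above the upper one.

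Genes known to carry RdDM spread widely around a median of 4.29 per kb, at the 70.9 percentile. BNS (AT1G73177) held 2 nucleosomes at 1.53 per kb, a value that turned from below to above the median gene when 1 kb of flank was added. PHE1 (AT1G65330), an imprinted MADS-box gene, held 7 at 6.48 per kb, and fell from 1.61 to 1.02 times the median gene with that flank. FWA (AT4G25530) held 16 at 3.90 per kb, and its top-scoring nucleosome lay on chromosome 4 at 13039775 to 13039928. SDC (AT2G17690) held 10 at 5.20 per kb, and the DNA demethylase gene ROS1 (AT2G36490) held 35 at 5.07 per kb. FWA, SDC, ROS1 and BSH were named after their values had been seen.

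Polycomb-silenced developmental genes had the lowest median of the 7 lists, 2.29 per kb, 0.581 of the random median and at the 0.0200 percentile. Of its 10 members 6 lay below the lower quartile of matched genes and 1 above the upper one. The floral organ gene PI (AT5G20240) held 3 nucleosomes at 1.15 per kb, on chromosome 5 at 6830623 to 6830761, 6830847 to 6830989 and 6831029 to 6831205. AG (AT4G18960), which specifies stamens and carpels, held 8 at 1.41 per kb. Its density fell from 0.349 to 0.0895 of the median gene among nucleosomes scoring at or above the median, where 0.176 per kb were left. With 1 kb of flank on both sides AG stood at 0.529 of the median gene. The 5 MADS-box members, which are the 5 sparsest of the list and were singled out after the values had been seen, had a median of 1.81 per kb at the 0.0500 percentile, among them FLC (AT5G10140) with 11 nucleosomes. The other members had a median of 3.73 per kb at the 37.2 percentile, inside the random range, and ABI3 (AT3G24650) held 21 at 5.50 per kb.

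Seed and pollen genes had the highest median, 5.54 per kb, 1.37 times that of random lists and at the 99.4 percentile, with 8 of 10 members above the upper quartile. SESA1 (AT4G27140), a seed storage albumin, held 5 nucleosomes at 7.11 per kb, and turned from 1.76 to 0.810 times the median gene with 1 kb of flank on both sides but reached 2.90 times among nucleosomes scoring at or above the median. VGD1 (AT2G47040), a pectin methylesterase of pollen tubes, held 15 at 6.40 per kb. With 1 kb of flank on both sides the list fell to 1.18 times, at the 90.6 percentile. Photosynthesis genes (4.54 per kb, 81.4 percentile) and housekeeping genes (4.07 per kb, 58.9 percentile) lay inside the random range. Among nucleosomes scoring at or above the median, the photosynthesis list turned from 1.13 to 0.725 times the random median (6.14 percentile), still inside the range. In it, RBCS1B (AT5G38430) held 6 nucleosomes at 2.79 per kb, and LHCA1 (AT3G54890) held 9 at 5.38 per kb. RBCS1B went from 0.691 to 0.236 of the median gene in that higher-scoring set, where 0.464 per kb were left. This change lay within its spread. In the housekeeping list UBC9 (AT4G27960) held 6 at 3.05 per kb and UBQ10 (AT4G05320) held 13 at 5.57 per kb, and UBQ10 turned from 1.38 to 0.873 times the median gene in the higher-scoring set. Photosynthesis genes carried lower scores, with a median of 0.732 at the 0.470 percentile of random lists.

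**Figure D5:**
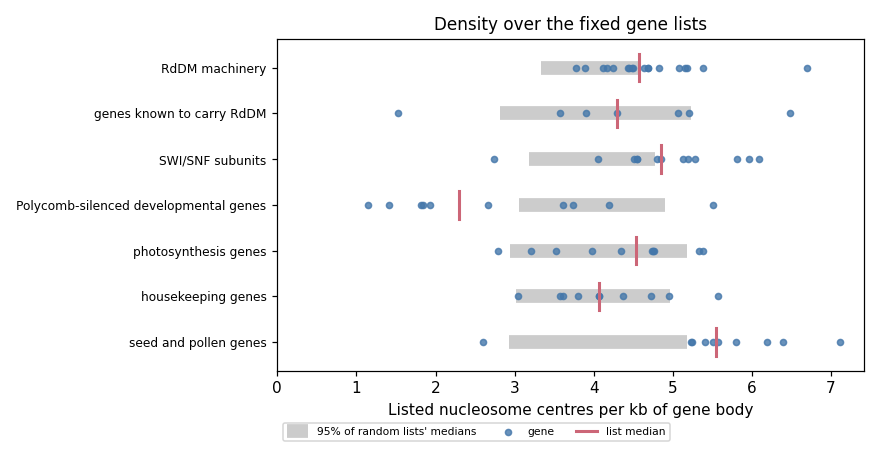
Listed nucleosome centres per kb of gene body (horizontal axis) for the members of 7 gene lists, as points, with the list median in red and the central 95% of medians of matched random lists in grey. Polycomb-silenced genes have a median of 2.29 per kb, below their grey bar, and seed and pollen genes 5.54 per kb, above it.

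Over all 27444 protein-coding genes the median density was 4.03 per kb (quartiles 3.05 and 5.07). Among the 14444 genes of 2 kb or longer, 7 held no listed nucleosome centre. These were AT1G02610, AT4G19645, AT2G01818, AT1G50670, AT5G10946, AT1G40086 and AT2G05655. The next lowest were AT1G39070 with 3 nucleosomes at 0.241 per kb, AT2G45660 with 1 at 0.276 per kb and AT5G42170 with 1 at 0.278 per kb. AT2G45660 is AGL20, also called SOC1, a MADS-box gene that promotes flowering. The highest density was that of AT2G15110, with 22 nucleosomes at 9.47 per kb covering 98.7% of the gene. It was followed by AT1G17250 (RLP3, a receptor-like protein gene) at 9.25 per kb, AT3G61720 at 9.21 per kb, AT2G07599 at 9.10 per kb and AT1G46696 at 9.04 per kb. AT3G29080, AT1G51172, AT2G07681 (ABCI4), AT3G42060 and AT1G40390 lay between 8.58 and 8.89 per kb. Of the lowest genes, AT1G40086, AT2G05655 and AT1G39070 lay in gene-poor windows, and of the highest AT3G42060 and AT1G40390 did. Whether repeated or organelle-like sequence affected the counts of these extreme genes was not tested. Among nucleosomes scoring at or above the median, AT3G29080 fell to 1.01 times the median gene, AT1G17250 to 1.12 times and AT2G07599 to 1.68 times.

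The highest score, 0.991, belonged to a nucleosome on chromosome 3 at 13869884 to 13870044, in intergenic sequence. Of the next 4, 2 lay in AT2G08986 on chromosome 2, at 3625428 to 3625563 and at 3623485 to 3623611. The others lay on chromosome 3, at 16718931 to 16719069 within 1 kb of a protein-coding gene and at 22314169 to 22314298 in AT3G60360.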

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

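The alternatives with gene flanks on both sides, the share covered, windows of 250 kb, sequence without long unlisted stretches, flanks of 500 bp and 2 kb, and the Polycomb list without MADS-box genes were chosen after seeing the data. Of the results that answer a comparison, 51 alternative values kept their call or stayed within their spread, and 45 of these also kept their direction. Of the rest, 3 moved beyond their spread, 1 reversed, 4 gained a call and 5 lost one. For single named genes 45 stayed within their spread and 42 of these kept their direction, while 4 moved beyond it and 1 reversed. The values that turned without a call were, among nucleosomes scoring at or above the median, photosynthesis genes (0.725 of the random median, 6.14 percentile), snoRNA and snRNA genes (1.07), UBQ10 (0.873), UBC9 (1.03) and the difference in mean spacing (-0.270 bp). With 1 kb of flank they were photosynthesis genes (0.961), housekeeping genes (0.855) and SESA1 (0.810), and by any overlap miRNA genes (0.988). Among nucleosomes scoring at or above the median the first spacing peak moved to 185.3 bp and the mean spacing to 183 bp, other non-coding RNA genes turned to 1.02 times the shifted count, the RdDM machinery rose to 1.23 times the random median and past the limit, and SWI/SNF subunits, at 1.23 times, lost their call. In genes of 2 kb or longer the trough at gene ends moved to -33 bp. By any overlap snoRNA and snRNA genes fell to 0.758, outside the shifted range, and tRNA genes to 1.70. With 1 kb of flank on both sides the RdDM machinery reached 1.19 times and passed the limit, SWI/SNF subunits at 1.19 and seed and pollen genes at 1.18 times lost their calls, and BNS turned to 1.32 times the median gene. By share covered the RdDM machinery reached 1.15 times and passed the limit. Without matching SWI/SNF subunits, at 1.20 times, lost their call, and the RdDM machinery stood at 1.13 times. Without its MADS-box genes the Polycomb list stood at 0.950 of the random median, inside the range. As these are the 5 sparsest members, leaving them out had to raise the median. The cause of the other changes was not tested.

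Alternatives that need a value per library or a strand were not run: the overlap of libraries at 1 bp or 80%, other scalings, fold limits of 1.5 or 3, pseudocounts, filters on summed value and the upstream kb alone. No paired analysis was possible because the list has no genotype and there was 1 library per genotype. The unknown depth limits every density, since a gene without a listed nucleosome cannot be told from one under the caller's limit.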

Other observations

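Gene families differed in density beyond the fixed lists. Groups of at least 10 protein-coding genes with a shared symbol were formed after the list results had been seen, and 172 groups were tried. Of these, 57 (33.1%) fell outside the central 95% of matched random lists, 31 lower and 26 higher, where 5% is the share by chance. Members of a family often lie side by side, so the groups are not independent. Among the high groups, CHX cation exchangers (23 genes) had a median of 6.12 per kb, KCS enzymes of wax synthesis (21) 5.72, UGT glycosyltransferases (58) 5.58 and cytochrome P450 genes (CYP, 229) 5.12. Among the low groups, LOG enzymes of cytokinin activation (10) had 1.65 per kb, small cysteine-rich LCR genes (80) 2.07, SWEET sugar transporters (15) 2.31, JAZ repressors of jasmonate signalling (10) 2.30 and BGLU glucosidases (40) 2.72. The random medians for these groups lay near 4 per kb.

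A candidate explanation for these group differences is intron content, since exons and introns can differ in nucleosome density. Exons were not used here, so the number of transcript models per gene served as a stand-in, with the prediction written before its result was seen. Genes with 1 model were denser than genes with 3 or more in 10 of 10 length deciles, with a median ratio of 1.24 (range 1.04 to 1.42). The number of models also follows how strongly and how widely a gene is expressed, so this test does not separate introns from expression. The ratio was highest in the shortest decile, which had 7 genes with 3 or more models, and lowest in deciles 9 and 10, at 1.11 and 1.04. The comparison ran over all genes. No group's density was compared after allowing for its numbers of models, so the group differences themselves were not tested.

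Of the tests on the next patterns, the covered share, the thinning and the make-up of feature classes of gene-poor windows and the split of AGAMOUS-like genes by length were chosen after the results had been seen. The list has no genotype, so no explanation by the study's groups was tested for any of them.

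Gene-poor windows were 1.46 times as dense as the arms. Fewer genes and gene flanks do not account for the whole of this, since in intergenic sequence over 1 kb from protein-coding genes the ratio was 2.94 (95% interval 2.47 to 3.45), and over all feature classes the gene-poor density was 1.38 times (1.29 to 1.47) that given by its make-up of classes at arm densities. That make-up alone gave 1.06 times the density of arms, and within protein-coding genes and pseudogenes the densities were close (4.03 against 4.21 and 6.25 against 6.59 per kb). Chromosome 2 is not its only source, since the ratio was above 1 on each of the 5 chromosomes (1.26 to 1.55); leaving chromosome 2 out gave 1.46 (1.35 to 1.57), which says nothing of its densest region, as that counted as arm. Whether more overlapping calls for the same DNA account for it stays open: each chain of overlapping intervals counted once gave 1.04 (0.992 to 1.08), within the bound of 1.1 set beforehand, but gene-poor windows held 1.03 times the chains left after random thinning to arm density, so chains merge with density alone, and the covered share, 1.41 times as large (1.32 to 1.503), grows with added overlapping calls too; the handling of reads from repeats was not tested.

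Listed nucleosomes gathered on tRNA genes. Tandem arrays whose copies share reads do not account for this, since 397 tRNA genes with no other within 10 kb had 2.78 times the shifted count (range 0.834 to 1.18). Intervals centred on tRNA genes had a median length of 137 bp, inside the 136 to 139 bp of random sets. That met the bound written against footprints shorter than a nucleosome, but the list holds only 120 to 180 bp, so the test is void and such footprints, for example of RNA polymerase III factors, stay a candidate source. Dispersed identical tRNA copies also stay open.

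The 5 sparsest of the 10 Polycomb-silenced genes were its MADS-box genes. The 94 other AGAMOUS-like genes, outside the list, the lowest named genes and 1 gene whose density had been seen before, but with PHE1 among the short ones, lay at the 8.60 percentile of random lists (median 3.78 against 4.07 per kb), which decided nothing. Split by length, the 39 of 2 kb or longer had 0.505 of the random median (1.99 against 3.95 per kb, 0 percentile). Taken alone, that goes with a low density of the family. The 55 under 2 kb had 1.18 times (4.97 against 4.197 per kb) and lay above the random range, at the 98.9 percentile. They argue against a low density across the whole family. A low density of long MADS-box genes may thus be the wider pattern. Whether the 39 long genes are themselves Polycomb-silenced was not examined, so their low density cannot tell a family effect from Polycomb silencing. The 5 remaining list members are also too few to rule out an effect of Polycomb silencing. Base composition and introns stay untested.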
